A study of Mus musculus with 8 samples.

How the data were processed

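Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in microglia from the mouse forebrain. Per the labels' protocols, brains were dissociated, myelin was removed and CD11b-positive cells were isolated on magnetic columns. Libraries were selected on a gel for fragments of 165 to 250 bp and sequenced single-end for 51 cycles. There were 4 libraries of Nlrp3 knockout mice and 4 of wild-type mice on a C57BL/6N background. The labels do not say whether the replicates of a genotype came from separate animals, so p-values measure only the spread between these samples, which may be technical in part.

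The submitters' processing notes name Bowtie2, HOMER, DESeq2 and the mm10 build, without versions. Per the file headers, the authors merged an IDR peak list of the wild-type libraries with an IDR peak list of the knockout libraries, where IDR keeps peaks that rank alike between replicates. Per the file headers, they then counted tags over the merged list with HOMER's annotatePeaks at the given peak sizes, taking at most 3 tags per position. The settings of alignment, any shift of read ends for the transposase, and the removal of duplicate or mitochondrial reads are not given in the sources used here. The deposited raw table holds these counts as whole tags per peak and library. The deposited normalized table holds a signal, tags per peak scaled by the authors to the same total number of tags in every library, per the file headers. Each normalized value equalled the raw count scaled by the header total to within 0.005. The same tables give each peak's nearest gene, its annotation and its distance to a transcription start site. Scaling to all tags does not correct for the share of tags that falls in peaks, which differed widely between libraries.

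The list held 67822 peaks with a median width of 268 bp (101 to 2280 bp). Of these, 51215 came from both IDR lists, 11060 from the wild-type list only and 5547 from the knockout list only. The 117 peaks without a gene held 0.13% of the tags in peaks and stayed in the peak test but out of the gene sums. All 8 value columns of each table were matched to their samples by name. Gene coordinates came from a RefSeq gene table of the matching assembly. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom over peaks was at least 1.17, for knockout replicates 1 and 2.

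The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM scaling, filterByExpr at its minimum count of 10, and a Benjamini-Hochberg adjusted p under 0.05. All 8 libraries entered one model with genotype as the only term. Levels are given as CPM, tags relative to all tags in tested peaks, after TMM scaling, as mean ± SD with 4 libraries per genotype, and fold changes are log2 of knockout over wild type. Tags were also summed over all peaks assigned to a gene and tested in the same way. Of 16095 genes with a peak, 15476 were tested, with a median of 3 peaks each. A gene named here is the one the deposited table assigns to a peak. Gene expression was not measured in these samples.

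The 21 gene lists were fixed before the data were examined, as were the main tests, the alternatives not named below as added, and the rule for named genes. They covered homeostatic microglia, disease-associated microglia, interferon response, antigen presentation, inflammatory cytokine and NF-kB, inflammasome and pyroptosis, glutamine and glutamate metabolism, TCA cycle and alpha-ketoglutarate, alpha-ketoglutarate-dependent chromatin enzymes, glycolysis, cholesterol and lipid handling, phagocytosis and amyloid uptake, lysosome and autophagy, cell cycle, immediate early and dissociation stress. A further 6 lists held markers of other cells: neuron, astrocyte, oligodendrocyte lineage, endothelial and mural, border macrophage and monocyte, granulocyte and lymphocyte. They named 417 genes, of which 364 were measured. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry beside it, and adjusted over the 21 lists. These tests read voom log2 values of the summed tags, while medians and means of lists were taken over the members' edgeR log2 fold changes. Fry tests whether a list's genes move one way on balance and does not compare the list with other genes.

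Named peaks were every tested peak in the Nlrp3 gene or within 5 kb of it or assigned to it. In each direction they were also the 15 with the largest fold change that passed the test, held a mean of at least 20 tags per library and had no overlap between genotypes. Named genes were the 5 with the smallest p in each direction, the 3 list members with the smallest p, and list members that passed. Shares of promoters among peaks that rose or fell were compared with those among tested peaks not called, by Fisher's exact test, two-sided. The share of changed peaks near Nlrp3 was compared by the same test with that of all other tested peaks. Library measures were compared with an exact permutation test, two-sided, over the 70 splits of the libraries, where the smallest possible p is 0.0286. Where a genotype had no tag in a peak, the fold is a lower bound against 3 tags over the group. Intervals have 95% coverage and, like the bounds, cover counting error only, since amplified reads are not independent molecules.

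The test was tested on simulated counts drawn from the real means and library sizes, with 200 features changed in each of 3 sets. With each peak's own dispersion, edgeR recovered 2.67%, 36% and 95.3% of peaks changed 1.5-fold, 2-fold and 4-fold among 58135 peaks, and 14% of its calls (57 of 408) were false, above the 5% that the threshold aims at. With dispersion on the trend, 4.81% were false. DESeq2 gave 4.14% false calls at peaks with each peak's own dispersion. For 15476 genes, edgeR recovered 50.7%, 86.7% and 98.7% at the same folds, with 7.52% false calls. In a simulated set of lists, the 1 list changed 1.2-fold was called and none of the others was. The simulation did not copy the correlation between genes of a real list. In the real data this correlation was estimated at 0.307 for the immediate early list and 0.154 for the homeostatic list, above camera's preset value. The simulated set therefore cannot tell how often camera calls unchanged lists in these data.

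Alternatives fixed in advance were DESeq2 1.42.0, its size factors in edgeR, scaling to all tags, loess offsets, no filter or a mean of at least 20 tags, the replicate number as a block, limma on the normalized values with a pseudocount of 1 or 5, leaving out each library, leaving out chromosomes X and Y, chromosome Y tags as a covariate, leaving out 10 Mb around Nlrp3, and other peak assignments, promoter definitions and windows. Alternatives added after seeing the data were leaving out knockout replicates 1 and 2, voom with quality weights, robust moderation in edgeR, a term for libraries above or below the median share of tags in peaks, and leaving out chromosome segments. These segments were also defined after seeing the calls: called peaks at most 2 Mb apart were chained, and chains of at least 4 calls were kept. Motif and GC analyses were planned and need genome sequence, which was not used here.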

Results

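Accessible chromatin was profiled by ATAC-seq in CD11b-positive microglia, the resident macrophages of the brain, isolated from the forebrain of wild-type and Nlrp3 knockout mice. NLRP3 is the sensor protein of an inflammasome, a complex that activates caspase-1 and the maturation of IL-1β. The study concerns NLRP3 and the use of glutamine by microglia in Alzheimer's disease, and the comparison asks how loss of Nlrp3 changes accessibility across the genome. Each genotype had 4 libraries. Total tags ranged from 11325865 (knockout replicate 3) to 15521580 (wild-type replicate 4), and the genotypes did not differ beyond the spread (exact permutation p = 0.2). The share of tags in the 67822 listed peaks was 17.5%, 9.79%, 12.8% and 14.4% in wild-type replicates 1 to 4. In knockout replicates 1 to 4 it was 6.68%, 4.96%, 20.9% and 26.2%. The knockout mean was 14.7% ± 10.5 (SD, n = 4) and the wild-type mean 13.6% ± 3.20, a difference of 1.07 points that did not exceed the spread (exact permutation p = 0.83, two-sided). The difference in the share of tags in peaks turned to -2.77 points without knockout replicate 4, to -1.01 without knockout replicate 3 and to -0.21 without wild-type replicate 2. The median tested peak held 8 tags in knockout replicate 2 and 36 in knockout replicate 4, so precision differed widely within the knockout group. On principal components of log2 CPM, the first component (30.0% of the variance) set knockout replicate 2 apart and the second (20.2%) knockout replicate 1. Tags on chromosome Y numbered 201 and 255 in wild-type replicates 3 and 4 and 88 in knockout replicate 3, against 1 to 13 in the other libraries. The 4 wild-type libraries thus cannot all be technical replicates of the same sample. Whether each library came from its own animal stays unknown. The mix of libraries with many and few chromosome Y tags also differed between the genotypes.

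Both promoter peaks of the targeted gene were all but absent from the knockout. Nlrp3 lies on chromosome 11 from 59541569 to 59566955 (mm10). The promoter peak at 59541383 to 59541657 held 58 to 80 tags in each wild-type library (37.1 ± 3.17 CPM) and 1 tag in the 4 knockout libraries together. The ratio of wild type to knockout was 253.9, with an exact interval of 45.19 to 10060 (edgeR adjusted p = 3.81e-11). A second peak annotated to a start site, at 59542459 to 59542809, held 54 to 69 tags per wild-type library (34.0 ± 3.78 CPM) and 2 tags in the knockout libraries together, a ratio of 115.7 (31.69 to 960.7; adjusted p = 6.58e-11). The other 8 tested peaks in or near the gene did not pass, with log2 fold changes from -0.80 to -0.0095 and a lowest adjusted p of 0.563, at the intergenic peak 59538387 to 59538693 (17.0 ± 5.11 CPM in knockout, 29.4 ± 4.17 in wild type). These included 3 intronic peaks assigned to Nlrp3 and 2 assigned to the olfactory receptor gene Olfr222. Every library had the tags of its labelled genotype at the promoter peaks. Sequence deleted or replaced in the knockout would leave no tags there either, and the labels do not describe the construct. These counts therefore cannot tell lost accessibility from lost sequence.

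**Figure D1:**
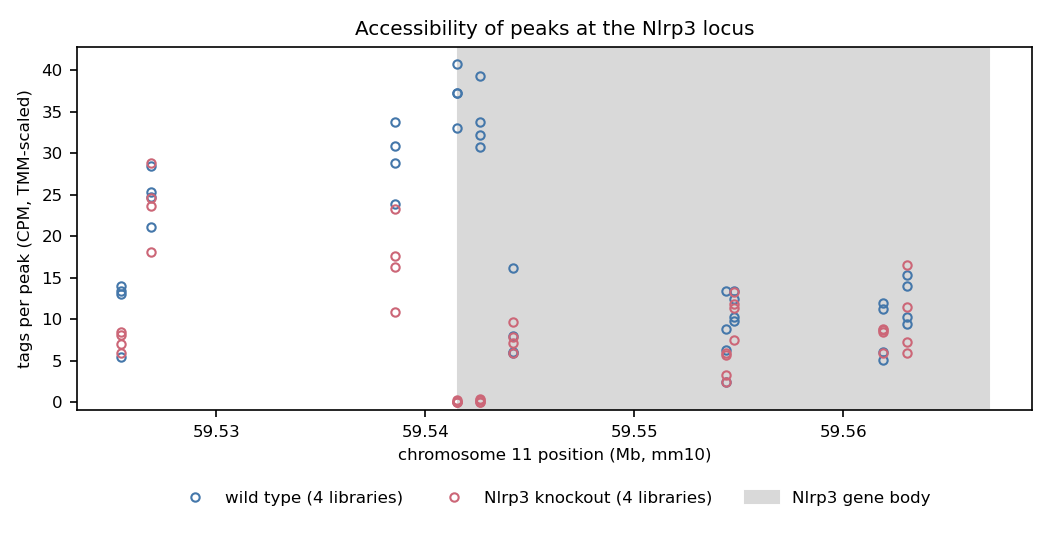
Accessibility (CPM after TMM scaling) of the 10 tested peaks at the Nlrp3 locus against their position on chromosome 11 (Mb, mm10), with 1 open circle per library (4 wild type in blue, 4 knockout in red) and the gene body shaded. The knockout libraries sit near 0 at both promoter peaks, where the wild-type means are 37.1 and 34.0 CPM, and overlap the wild type at the other peaks except the intergenic one at 59538387.

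Across the genome, 99 of 58135 tested peaks changed, 32 higher and 67 lower in the knockout (edgeR quasi-likelihood test, adjusted p under the threshold of 0.05), and 2808 had an unadjusted p under 0.05. Of the 99, 95 exceeded 2-fold and 94 had no overlap between genotypes, properties that the test selects for, since it recovered 2.67% of 1.5-fold and 36% of 2-fold changes in simulated counts. Over all tested peaks, 3.17% had no overlap, against 2.86% by chance. Peaks that rose came from the knockout list only (19) or from both lists (13), and peaks that fell from the wild-type list only (37) or from both (30). The lists were made from these same libraries, so this match was nearly fixed in advance. Among tested peaks not called, 1804 came from the knockout list only and 6206 from the wild-type list only. Peaks listed in wild type alone were thus more numerous, which bears on the balance of higher and lower calls. Changed peaks lay close together. After the calls were seen, those at most 2 Mb apart were chained, and 65 of the 99 fell into 6 segments that hold 1190 tested peaks (2.05%). The segments lie on chromosome 11 (113101730 to 120571465, 17 changed peaks), chromosome 9 (103678501 to 107757733, 19), chromosome 6 (136464379 to 137697175, 10, and 47650497 to 51171233, 6), chromosome 18 (73501934 to 75426357, 9) and chromosome 4 (154877926 to 155831377, 4). In simulated counts with each peak's own dispersion, 14% of the calls of this test were false. The count was 65 with DESeq2, 65 without knockout replicate 3, 246 without knockout replicates 1 and 2, and 19 with scaling to all tags, where 9 were higher and 10 lower. Without knockout replicate 4 it was 123, and the balance turned, with 66 higher and 57 lower. The count of changed peaks in chained segments was 36 with DESeq2 and 36, 43 and 43 without knockout replicate 3, wild-type replicate 3 and wild-type replicate 4, and 173 without knockout replicates 1 and 2. Without knockout replicates 1 and 2, the remaining knockout libraries all had a higher share of tags in peaks than any wild-type library.

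**Figure D2:**
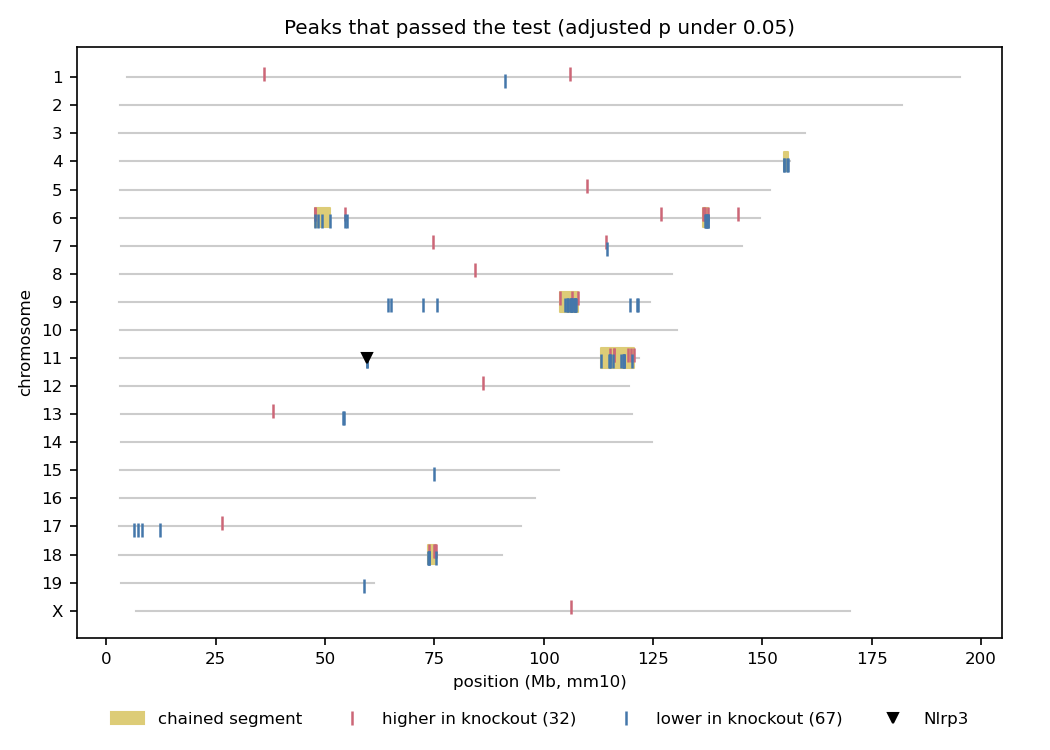
Positions (Mb, mm10) on each chromosome of the 99 peaks that passed the test, with ticks above the line for the 32 higher and below it for the 67 lower in knockout libraries, the 6 segments shaded and Nlrp3 marked by a triangle. Chromosomes 9, 6 and 11 carry 26, 21 and 19 of the changed peaks, and 65 of the 99 lie in the segments.

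Apart from those of Nlrp3, most of the named peaks that fell lay on chromosome 9. The intergenic peak assigned to Cacna2d2, an auxiliary subunit of voltage-gated calcium channels (9:107372546–107372792), had 1.89 ± 2.72 CPM in knockout against 21.8 ± 3.70 in wild-type libraries (log2 -4.49, SE 0.48, adjusted p = 3.86e-06). An intronic peak of Atp2c1, a Golgi calcium and manganese pump (9:105502455–105502714), had 1.98 ± 1.64 against 27.3 ± 4.35 CPM (log2 -4.14, SE 0.34), with knockout replicate 2 above the other knockout libraries. Peaks of Dusp7, a phosphatase of MAP kinases, fell at an intron (9:106332809–106333063, log2 -3.24, SE 0.42) and between genes (9:106394674–106394948, log2 -2.43, SE 0.24). Peaks assigned to Mapkapk3, a kinase activated by MAP kinases, fell at 2 intronic sites (9:107278588–107278870, log2 -1.96, and 9:107280045–107280520, log2 -1.60). Outside the rule for named peaks, a further intronic Mapkapk3 peak (9:107280869–107281110, log2 -2.57) was lower. Its promoter peak was lower too (9:107289771–107290010, log2 -1.20, SE 0.16, edgeR adjusted p = 0.000103). Also on chromosome 9, outside the segment, an intergenic peak assigned to the sodium channel gene Scn10a (9:119737098–119737364) fell by 3.10 and an intronic peak of Mns1 (9:72449481–72449727) by 2.11 on the log2 scale. On chromosome 6, intergenic peaks assigned to Strap (6:137696814–137697175, log2 -2.22) and Mir148a (6:51170957–51171233, log2 -1.95) were lower. On chromosome 11, intergenic peaks assigned to Gm11747 (11:118457065–118457334, log2 -1.98) and the dynein gene Dnah17 (11:118145746–118146110, log2 -1.85) were lower, as was an intronic peak of Hspa12a on chromosome 19 (19:58838710–58839197, log2 -1.58).

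Among peaks that rose, an intron of Fbf1, which encodes a protein of the ciliary base (11:116162169–116162437), went from 1.63 ± 1.43 CPM in wild type to 31.2 ± 3.63 in knockout libraries (log2 4.08, SE 0.34, adjusted p = 3.92e-08). An intergenic peak near Mturn (6:54679219–54679472) went from 1.59 ± 0.70 to 20.2 ± 7.38 CPM (log2 3.70, SE 0.36). An intron of Eps8, an adaptor of the actin cytoskeleton (6:137630534–137631246), was higher by 3.09 on the log2 scale (SE 0.30), and an exon-annotated peak assigned to the minor spliceosome gene Snrnp48 (13:38192884–38193134) by 2.44 (SE 0.36), each with 1 wild-type library apart from the other 3. The promoter of Pgk1, the glycolytic enzyme phosphoglycerate kinase (X:106186845–106187118), had 97.05 to 103.8 CPM in the knockout libraries (SD 2.86) against a mean of 45.7 ± 7.53 in wild type (log2 1.11, SE 0.14, adjusted p = 3.69e-05). The other tested peak of Pgk1, at X:106171217–106171433, had a log2 fold change of -0.023 (adjusted p = 1). Smaller rises with passing adjusted p were found at Dusp1, a stress-induced phosphatase (17:26500674–26501338, log2 1.19), Slco3a1, an organic anion transporter (7:74684015–74684303, log2 1.19), the microRNA gene Mir3074-2 (8:84213611–84214441, log2 1.36), Gm7160 (1:105965183–105965566, log2 1.40), 2010010A06Rik (18:75174287–75174648, log2 1.5), E330021D16Rik (6:136464379–136464669, log2 1.25), Mir5098 (11:119874871–119875181, log2 1.10) and Tmem104 (11:115219244–115219705, log2 1.09). At Dusp1 and Slco3a1, 1 library stood apart from the others of its genotype. A pair of peaks assigned to Rn4.5s, a small RNA gene of a repeated family whose tags can be split between copies, rose by 1.63 (6:47651089–47651358) and 1.54 (6:47650497–47651040) on the log2 scale, with wild-type replicate 4 at 38.2 CPM in the first against 9.84 to 14.2 in the other wild-type libraries. Of the named peaks, both Nlrp3 promoter peaks and those of Fbf1, Mturn, Cacna2d2 and Atp2c1 passed under every alternative that tested them, each of the others lost the call under at least 1, and the Tmem104 peak lost it under 13 of 24. The Rn4.5s peaks and the intronic Dusp7 peak did not pass with robust moderation, an alternative added after seeing the data.

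Changed peaks of 4 genes went in both directions, and the following were chosen after their values were seen. A peak in the 3' UTR of Mturn (6:54699489–54699754) was lower (log2 -2.97, SE 0.46, edgeR adjusted p = 0.00132), opposite to the intergenic Mturn peak, and an intronic peak of Tmem104 (11:115192124–115192480) was lower (log2 -1.41, SE 0.30, adjusted p = 0.048), opposite to the other Tmem104 peak and with the genotypes overlapping. An intronic peak of Pde6h (6:136961419–136961703) was higher (log2 2.65, SE 0.41) and an intergenic peak assigned to it (6:136988562–136988857) lower (log2 -1.93, SE 0.36). Of the peaks assigned to Smad7, an inhibitor of TGF-beta signalling, that at 18:75426082–75426357 was higher (log2 2.20, SE 0.42) and that at 18:75414241–75414469 lower (log2 -1.47, SE 0.24). Without 1 library, the Mturn peak in the 3' UTR, the intronic Pde6h peak and the lower Smad7 peak kept the call. The lower Pde6h peak lost it without wild-type replicate 4 (adjusted p = 0.103) or knockout replicate 3 (0.138; range 0.00242 to 1), and the higher Smad7 peak without wild-type replicates 1 (0.0794), 3 (0.0807) or 4 (0.103) or knockout replicates 3 (0.0561) or 4 (0.109; range 0.00143 to 1). The intronic Tmem104 peak lost it without any 1 library but wild-type replicate 1 and knockout replicate 1 (0.0595 to 0.484; range 0.00751 to 1).

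Of the peaks named by the rule, 10 lost the call when 1 library was left out. The Slco3a1 and Hspa12a peaks lost it without knockout replicate 3 (adjusted p = 0.0529 each, ranges 0.000949 to 1 and 0.000466 to 1). The Mir3074-2 peak lost it without wild-type replicates 3 (0.0786) or 4 (0.0618; range 0.000524 to 1), and the Mapkapk3 peak at 9:107280045 without wild-type replicate 1 (0.0628) or knockout replicates 3 (0.118) or 4 (0.0688; range 0.000314 to 1). The Dusp1 peak lost it without wild-type replicates 2 (0.0702), 3 (0.081) or 4 (0.102) or knockout replicate 3 (0.221; range 0.00118 to 1). The Gm7160 peak lost it without wild-type replicates 1 (0.0567), 3 (0.0882) or 4 (0.0758; range 0.00289 to 1), and the 2010010A06Rik peak without wild-type replicates 1 (0.0906), 2 (0.0501) or 3 (0.118; range 0.00302 to 1). The E330021D16Rik peak lost it without wild-type replicates 2 (0.0833), 3 (0.0739) or 4 (0.0679) or knockout replicates 3 (0.0709) or 4 (0.122; range 0.0014 to 1). The Mir5098 peak lost it without wild-type replicates 2 (0.124), 3 (0.11) or 4 (0.131) or knockout replicates 2 (0.0527) or 4 (0.175; range 0.0121 to 1). The Tmem104 peak lost it without any 1 library but knockout replicate 2 (0.0519 to 0.262; range 0.0194 to 1).

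Changed peaks lay at promoters less often than tested peaks that were not called. Promoters made up 2 of the 32 higher peaks (6.25%) and 5 of the 67 lower peaks (7.46%), against 21.3% of the 58036 peaks not called. The odds ratio was 0.246 for higher peaks (interval 0.0285 to 0.970, Fisher's exact adjusted p = 0.0483) and 0.298 for lower peaks (0.0934 to 0.733, adjusted p = 0.00808). Fisher's test takes peaks as independent, while 65 of the 99 changed peaks lay in 6 segments, so its p and intervals can be too narrow. Calls were mostly of changes above 2-fold, so these shares do not speak for smaller changes. By Fisher's exact test, the call was lost in both directions with scaling to all tags (odds ratios 0.462 and 0.924) and, for higher peaks, with DESeq2, where the odds ratio was 0.185 (adjusted p = 0.0652, range 0.000106 to 1 over its alternatives). By Fisher's exact test, the promoter share among higher peaks lost the call without wild-type replicate 2 (odds ratio 0.324, adjusted p = 0.143), wild-type replicate 3 (0.186, p = 0.0666) or knockout replicate 3 (0.356, p = 0.201). For lower peaks, by the same exact test, promoter share among changed peaks lost it without wild-type replicate 1 (0.608, p = 0.297), wild-type replicate 3 (0.347, p = 0.0649) or knockout replicate 3 (0.394, p = 0.172).

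Changed peaks were also counted around the targeted gene. Within 10 Mb of Nlrp3, 2 of 909 tested peaks changed (0.22%), both being the Nlrp3 promoter peaks, against 97 of 57226 elsewhere (0.17%). The odds ratio was 1.30 with an interval of 0.155 to 4.83, so no difference was detectable (Fisher's exact p = 0.669).

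Summed over the peaks of each gene, 33 of 15476 tested genes changed, 12 higher and 21 lower, and 923 had an unadjusted p under 0.05. Kcna6, a voltage-gated potassium channel, rose from 1.88 ± 0.74 to 26.1 ± 5.35 CPM (log2 3.72, SE 0.32, adjusted p = 5.48e-07). Pcbp4, an RNA-binding protein, rose by 3.63 (SE 0.40), Tmem108 by 2.47 (SE 0.34), Rn4.5s by 1.83 (SE 0.27) and Pgk1 by 1.01 (SE 0.11) on the log2 scale. Nlrp3 fell by 1.15 (SE 0.10, adjusted p = 5.48e-07) over its 8 peaks, Mapkapk3 by 1.00 (SE 0.097) over 12, Gm11747 by 1.04 (SE 0.11) over 4, and Cacna2d2 by 4.48 (SE 0.50) at 1 peak. The single peak of Tmem181a, an intron at 17:6272099–6272315, held 15 to 38 tags per wild-type library and 0 in every knockout library. It was at least 31.85-fold lower against the floor of 3 tags over the group, and the exact interval of the ratio had a lower limit of 25.44. Kcna6, Pcbp4, Cacna2d2 and Tmem181a passed under every alternative that tested them, while Rn4.5s did not pass with robust moderation (adjusted p = 0.575, range 7.54e-06 to 1). Rn4.5s lost the call under 5 alternatives, Tmem108 and Mapkapk3 under 4 each, and Nlrp3, Pgk1 and Gm11747 under 3 each. Of the 33 genes, 19 had a peak in the segments named above and 14 had none. The count was 5 with scaling to all tags, 21 without wild-type replicate 3 and 20 without knockout replicate 3. It was 70 without knockout replicates 1 and 2. The balance turned to more higher than lower genes without wild-type replicate 1 (22 and 20) or knockout replicate 4 (19 and 17). It also turned with scaling to all tags and with limma at a pseudocount of 1 (3 and 2 each).

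Of the 21 gene lists, 2 passed camera, both higher in the knockout, and neither passed with an estimated correlation. Medians and means of lists are those of the members' edgeR log2 fold changes. The list of immediate early and dissociation stress genes, which respond within minutes to cell isolation, had a median log2 fold change of 0.11 over 24 measured members (camera adjusted p = 0.000206; adjusted p = 0.733 with an estimated correlation and 0.605 with fry). The median was 0.0448 without wild-type replicate 3 and 0.175 without knockout replicate 4. Of these members, 1 rose and 0 fell over all genes tested: Atf3, a stress-induced transcription factor (log2 0.44, SE 0.089, edgeR adjusted p = 0.0249). By DESeq2, 2 members passed. Adjusted over the list alone, 5 rose, namely Atf3, Jund (log2 0.77), Dusp1 (log2 0.32), Klf2 (log2 0.51) and Fosb (log2 0.22). Atf3 missed the threshold without wild-type replicate 2 (adjusted p = 0.131), 3 (0.131) or 4 (0.0706) or knockout replicate 1 (0.124), 2 (0.0522) or 3 (0.0976), within a range of 0.000489 to 1 over its alternatives. Jund, which did not pass over all genes (adjusted p = 0.0559), did so without wild-type replicate 1 (0.00222) or knockout replicate 4 (0.000128), within a range of 0.000128 to 1. The list's mean log2 score was 0.205, 0.252 and 0.195 in knockout replicates 1 to 3 but -0.0842 in knockout replicate 4, and 0.0897, -0.0421, -0.0915 and 0.0439 in the wild-type libraries (exact permutation p = 0.171). The highest 2 scores were those of the libraries with the lowest share of tags in peaks.

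The homeostatic list, which holds genes of resting microglia, had a median log2 fold change of 0.060 over 20 measured members (camera adjusted p = 0.0237; adjusted p = 0.733 with an estimated correlation and 0.605 with fry). The median was 0.0388 without wild-type replicate 2, 0.025 without knockout replicate 4 and 0.0958 without wild-type replicate 1. The mean log2 score of the homeostatic list was 0.0912, 0.00952, -0.0856 and -0.0151 in wild-type replicates 1 to 4 and 0.0401, -0.00538, 0.0568 and 0.112 in knockout replicates 1 to 4 (exact permutation p = 0.286). Of these members, 0 passed over all genes in edgeR, DESeq2, voom or limma, with 5 at an unadjusted p under 0.05 in edgeR. Adjusted over the list alone, 1 rose: Csf1r, the receptor for the survival factor CSF1 (log2 0.26, SE 0.077). Tmem119 (log2 0.24) and Egr1 (log2 0.27), which the immediate early list holds too, were next. At an unadjusted p under 0.05 stood 0 of the 21 lists with an estimated correlation and 1 with fry. Neither the immediate early nor the homeostatic list passed camera with scaling to all tags (adjusted p = 0.263 and 0.746) or with loess offsets (0.491 and 0.53, medians 0.021 and 0.0178). With promoter peaks only, both missed it too (camera adjusted p = 0.959 and 0.0555, medians 0.00978 and 0.155). With the share of tags in peaks as a term, the homeostatic list had a camera adjusted p of 0.0974 (median 0.0471). The immediate early list had 0.000272 (median 0.106) in that setting, whose term is balanced between the genotypes. With scaling to all tags, the medians of the voom values that camera reads were -0.113 and -0.2, against -0.224 over all genes, and those of the edgeR values 0.179 and 0.173, against 0.0884 over all genes. The homeostatic list was lost without wild-type replicate 3 (adjusted p = 0.244), wild-type replicate 4 (0.0797) or knockout replicate 4 (0.541), within a range of 0.00226 to 0.746. Without knockout replicates 1 and 2 the immediate early list had a median of 0.11, as with all libraries, and an adjusted p of 0.0581, within a range of 1.58e-12 to 0.959.

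Lists tied to the study's question did not pass camera. By the exact permutation test on mean log2 scores, not adjusted over lists, p was 0.0857 for glutamine and glutamate metabolism. It was 0.0571 for the TCA cycle and alpha-ketoglutarate list, both being lower in the knockout. These p were the lowest of the 21 lists, below those of the immediate early (0.171) and homeostatic (0.286) lists. Among 21 lists, a lowest p of this size can arise by chance. The TCA cycle score of knockout replicate 4 was 0.00873, within the wild-type range of -0.0864 to 0.0388. Without knockout replicates 1 and 2 that list's median log2 fold change was 0.00539 (camera adjusted p = 0.962). Glutamine and glutamate metabolism had a median log2 fold change of -0.0495 over 21 measured members (adjusted p = 0.685), and 0 members rose or fell by edgeR, DESeq2, voom or limma, with 3 at an unadjusted p under 0.05; the smallest p were those of the glutamine transporter gene Slc1a5 (log2 -0.62, SE 0.20), the glutamate transporter gene Slc1a3 (0.33, SE 0.11) and the glutamine synthetase gene Glul (0.18, SE 0.075). The TCA cycle and alpha-ketoglutarate list had a median of -0.019 over 23 members (adjusted p = 0.487), with 0 passing by the same tools, 2 at an unadjusted p under 0.05, and the lowest p for Sdhd (log2 -0.86, SE 0.25), Dld (-0.50, SE 0.20) and Ogdh (-0.15, SE 0.12). The alpha-ketoglutarate-dependent chromatin enzymes had a median of 0.026 over 20 members (adjusted p = 0.685), led by Kdm6a (0.33), Kdm6b (0.13) and Kdm3b (-0.22), with 0 passing by the same tools and 1 at an unadjusted p under 0.05. In the inflammasome and pyroptosis list, 1 of 20 members fell, Nlrp3 itself, with Nlrp1b at 0.21 and Il1rn at -0.45; its median was 0.0011 and its mean -0.057, and the test pointed down (adjusted p = 0.685). Glycolysis had 1 of 20 members higher, Pgk1, with Hk3 at -0.29 and Pfkp at -0.53, and a median of 0.0035 (adjusted p = 0.685).

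Among 8 lists of microglial states and functions, 0 members passed by edgeR, DESeq2, voom or limma. At an unadjusted p under 0.05 in edgeR stood 2 disease-associated, 1 interferon, 1 antigen presentation, 2 phagocytosis and 1 cholesterol members, and 0 of the cytokine, lysosome and cell cycle lists. Disease-associated microglia genes had a median of -0.022 and a mean of -0.0063, with a test pointing up (24 members, adjusted p = 0.878; Cd9 0.19, Fabp5 0.26, Timp2 -0.13). The interferon response had a median of -0.016 and a mean of 0.019, with a test pointing up (17 members, adjusted p = 0.815; Zbp1 0.24, Ifi204 0.20, Ifit1 0.33) and antigen presentation a median of 0.037 (15 members, adjusted p = 0.685; B2m 0.31, Tapbp -0.25, H2-K1 0.15). Inflammatory cytokine and NF-kB genes had a median of 0.026 (19 members, adjusted p = 0.487; Cd40 0.36, Tnfaip3 0.10, Nos2 0.22). Phagocytosis and amyloid uptake had a median of 0.036 (25 members, adjusted p = 0.33; C1qb 0.32, C1qa 0.24, Scarb1 0.13); the list passed without wild-type replicate 1 (adjusted p = 0.0249) and with promoter peaks only (0.00992), within a range of 0.00992 to 0.808. Cholesterol and lipid handling had a median of -0.027 (22 members, adjusted p = 0.685; Nr1h2 -0.46, Plin2 -0.31, Nr1h3 -0.29), lysosome and autophagy -0.029 (25 members, adjusted p = 0.777; Sqstm1 0.19, Lamp1 -0.25, Tmem106b -0.40) and the cell cycle -0.077 (21 members, adjusted p = 0.487; Plk1 -0.44, Ccne1 -0.16, Ccnd1 0.076).

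Markers of other cell types did not pass either, with 0 members passing by edgeR, DESeq2, voom or limma and 1 each of the neuron, oligodendrocyte, endothelial and border macrophage lists at an unadjusted p under 0.05. Medians were 0.025 for the neuron list (9 members, adjusted p = 0.685; Syt1 0.62, Tubb3 0.35, Slc17a7 0.21), 0.065 for the astrocyte list (11 members, adjusted p = 0.685; Id4 0.31, Ntsr2 0.41, Gjb6 0.34) and 0.10 for the oligodendrocyte lineage (10 members, adjusted p = 0.262; Mag 0.62, Mbp 0.14, Opalin 0.11). They were -0.0605 for endothelial and mural cells (8 members, adjusted p = 0.549; Acta2 -0.60, Flt1 -0.15, Cdh5 0.15) and 0.076 for granulocytes and lymphocytes (8 members, adjusted p = 0.685; Lck 0.24, Ms4a1 0.23, Cd3d 0.21). The border macrophage and monocyte list had a median of -0.00495 and a mean of 0.00985, with a test pointing up (14 members, adjusted p = 0.862; Ms4a7 0.60, Folr2 -0.38, Stab1 0.13). Knockout replicates 2 and 3 had the highest oligodendrocyte scores, 0.334 and 0.231, and the highest neuron scores, 0.259 and 0.203.

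**Figure D3:**
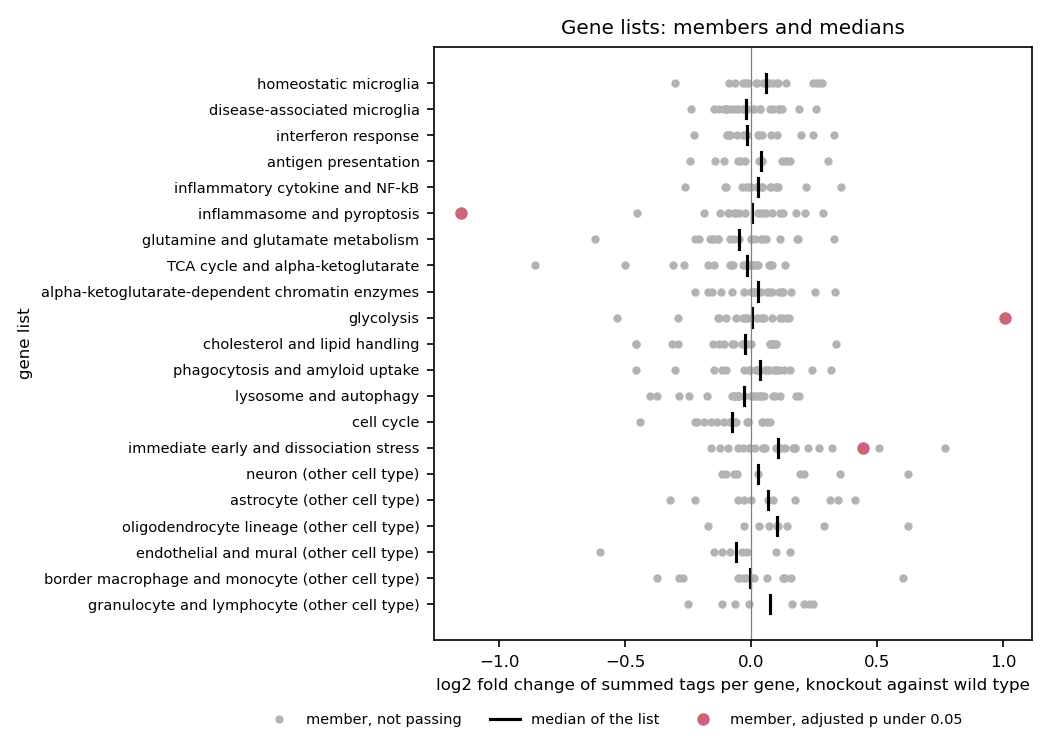
Log2 fold change (edgeR, knockout against wild type) of the summed tags of each measured member of the 21 gene lists, with 1 point per gene, red where the gene passed the test, and a black bar at the median of the list's points. The red points are Nlrp3 at -1.15, Pgk1 at 1.01 and Atf3 at 0.44, and the medians lie between -0.077 (cell cycle) and 0.11 (immediate early).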

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

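The limit used here was fixed before the data were examined. The check covered 100 groups of 4 libraries, at the named peaks, the named genes with the smallest p, total tags and the share of tags in peaks. In 9 groups, all at peaks, 1 library lay far from the other 3, by Dixon's ratio of the gap to the nearest library over the group's range. Chance gives about 5% of such groups.

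At the Eps8 peak, wild-type replicate 1 had 1.491 CPM against 2.80 to 2.85 in the other wild-type libraries. At the Snrnp48 peak, wild-type replicate 2 had 11.24 CPM against 1.49 to 2.85, and at the Rn4.5s peak at 6:47651089 wild-type replicate 4 had 38.2 CPM against 9.84 to 14.2. At the Dusp1 peak, wild-type replicate 1 had 17.4 CPM against 11.7 to 12.5. At the Slco3a1 peak, knockout replicate 4 had 27.17 CPM against 33.8 to 34.7. At the Atp2c1 peak, knockout replicate 2 had 4.429 CPM against 0.971 to 1.32. At the Nlrp3 promoter peak at 11:59541383, knockout replicate 4 had 0.3235 CPM, a single tag, against 0 in the other knockout libraries. At the intergenic Nlrp3 peak at 11:59525239, which did not pass, wild-type replicate 1 had 5.469 CPM against 13.09 to 13.97. At the Olfr222 peak at 11:59561786, which did not pass, knockout replicate 2 had 5.905 CPM against 8.45 to 8.78. At the peaks 11:59525239 and 11:59561786 the genotypes overlapped. No explanation was tested for any of these groups.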

How the results depend on the processing

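The settings chosen after seeing the data were those without knockout libraries 1 and 2, with quality weights, with robust moderation, with the share of tags in peaks as a term and without the chained segments, as were all values of chained segments. The GC corrections, with and without the block, and the motif alternatives were not run. Where no cause is given, the cause was not tested. Depth limits what the peak test can find: the median tested peak held 8 to 36 tags per library, and in simulated counts 36% of peaks changed 2-fold were recovered. Over all alternatives, values of 51 peaks named in the text kept their direction and side of the threshold in 993 cases, lost the call in 204 and turned in 30. For named genes these numbers were 1802, 35 and 31, with 8 gained calls, and for lists 378, 15 and 25, with 2 gained. Most of these genes and lists had not passed the main test, so their unchanged cases say little about the calls. The 2 lists that passed lost the call in 9 (homeostatic) and 6 (immediate early) of 20 alternatives each.

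The number of peaks changed in NLRP3 knockout, 99, was 65 with DESeq2 (64 shared), 19 with scaling to all tags (19 shared; 9 higher and 10 lower, 52.6% lower against 67.7%), 16 and 18 with limma on the normalized table at a pseudocount of 1 and 5, 65 with chromosome Y tags as a covariate and 246 without knockout libraries 1 and 2 (92 shared). It was 42 with a mean of at least 20 tags and 27 without the chained segments, both of which test fewer peaks. Leaving out 1 library gave 65 (knockout replicate 3) to 123 (knockout replicate 4, where 46.3% were lower). The other settings gave 81 (quality weights) to 140. The number of genes changed in summed accessibility, 33, was 5 with scaling to all tags, 5 and 4 with limma at a pseudocount of 1 and 5, 70 without knockout libraries 1 and 2, 9 without the chained segments and 8 with promoter peaks only, and 20 to 42 leaving out 1 library. The median log2 change, 0.00368 over peaks and 0.002 over genes, was 0.0989 and 0.0884 with scaling to all tags. With limma on the normalized table at a pseudocount of 1 and 5 it was -0.183 and -0.1 over peaks and -0.216 and -0.175 over genes. The changed peaks in chained segments, 65, were 36 with DESeq2, 173 without knockout libraries 1 and 2, 36 to 86 leaving out 1 library, and 62, 65 and 72 with gaps of 1, 3 and 5 Mb.

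Whether replicate numbers pair the samples was not settled. Deviations of same-numbered libraries correlated at -0.00784, 0.0962, -0.0083 and 0.147 for numbers 1 to 4. Libraries numbered 2 and 4 correlated best with their own number, and those numbered 1 and 3 did not. With the replicate block, 140 peaks were called (65 higher, 75 lower, 53.6% lower; 98 shared), 38 genes and 2 lists. Under the block, the odds ratio of changed peaks near Nlrp3 on chromosome 11 turned to 0.9122 and the log2 change of the Olfr222 peak at 11:59561786 to 0.0997 (0.09969). With a window of 20 Mb, the odds ratio of changed peaks near Nlrp3 on chromosome 11 was 0.6636. The odds ratio for promoter share among higher peaks was 0.462 with scaling to all tags (adjusted p = 1) and 0.1846 with DESeq2 (adjusted p = 0.0652), and 0.1166 to 0.3561 leaving out 1 library (adjusted p = 0.000106 to 1 over its alternatives). For lower peaks, promoter share among changed peaks was 0.9241 with scaling to all tags and 0.3017 to 0.6076 leaving out 1 library. The share of tags in peaks differed by -2.768 to 4.316 points leaving out 1 library.

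Of gene lists changed, 2 in the main test, 0 passed with an estimated correlation, 0 with fry, 0 with scaling to all tags, 0 with loess offsets, 1 with promoter peaks only (phagocytosis and amyloid uptake, not among the 2), 1 without knockout libraries 1 and 2 (homeostatic) and 1 with the share of tags in peaks as a term (immediate early). Leaving out 1 library gave 1 to 3. In lists that passed nowhere, the direction of the test turned in these settings, given with the median edgeR log2 change of the members. Camera reads voom values, whose median can differ in sign: in the main test it was 0.00572 for the interferon response and 0.00524 for border macrophage and monocyte genes, with a mean of -0.0197 for the latter. For disease-associated microglia it was -0.02347 with loess offsets, -0.04828 without knockout libraries 1 and 2, -0.01934 with the share term, and -0.061 to 0.03773 leaving out 1 library. For the interferon response it was -0.01081 with the share term and -0.02951 to 0.05838 leaving out 1 library. For inflammasome and pyroptosis it was 0.0257 without 10 Mb around Nlrp3, which leaves out Nlrp3 itself, -0.008436 without knockout libraries 1 and 2, and -0.01363 to 0.02844 leaving out 1 library. For lysosome and autophagy it was 0.0175 without knockout libraries 1 and 2 and -0.03305 to 0.00369 leaving out 1 library. For border macrophage and monocyte (other cell type) it was 0.1109 with promoter peaks only, -0.00637 with loess offsets, 0.01987 without knockout libraries 1 and 2, -0.0327 with the share term, and -0.05129 to 0.08063 leaving out 1 library. For glutamine and glutamate metabolism it was -0.009427 with promoter peaks only, for alpha-ketoglutarate-dependent chromatin enzymes -0.008665 with loess offsets and for neuron (other cell type) -0.04934 within 50 kb of the start site.

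At the locus, values that did not pass turned as follows. The Nlrp3 peak at 11:59526763 had a log2 change of 0.1232 with scaling to all tags, 0.1051 without knockout libraries 1 and 2, 0.003212 with quality weights, and -0.143 to 0.07332 leaving out 1 library. The Olfr222 peak at 11:59561786 had 0.0644, 0.04927 and 0.1381 in these 3 settings and -0.2034 to 0.2005 leaving out 1 library. The Olfr222 peak at 11:59562956 had 0.1706 with scaling to all tags, 0.2135 without knockout libraries 1 and 2, and -0.4112 to 0.08892. The Nlrp3 peaks at 11:59544025 and 11:59554643 had -0.3542 to 0.2002 and -0.2106 to 0.05654 leaving out 1 library. The Pgk1 peak at X:106171217, which did not pass either, had 0.01494 with DESeq2, 0.04872 with loess offsets, 0.0005647 with quality weights, 0.06803 with the share term, 0.09738 with the replicate block, and -0.2719 to 0.1717 leaving out 1 library.

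With limma on the normalized table, these list members that had not passed turned to values below 0, each of them above the median over genes. With a pseudocount of 1 and of 5, log2 changes were -0.03349 and -0.03124 for Cd9, -0.1267 and -0.1033 for H2-K1, -0.1212 and -0.1173 for Tnfaip3, -0.04027 and -0.0275 for Nlrp1b, -0.04594 and -0.04309 for Glul, -0.09726 and -0.09334 for Kdm6b, and -0.08476 and -0.07913 for Scarb1. They were -0.008757 and -0.002615 for Sqstm1, -0.1558 and -0.1505 for Ccnd1, -0.09442 and -0.08967 for Mbp, -0.165 and -0.1433 for Opalin, -0.03957 and -0.02784 for Cdh5, and -0.1073 and -0.09829 for Stab1. With a pseudocount of 1 only, Nos2 had -0.0009261, Lck -0.007761 and Cd3d -0.04628. With promoter peaks only, Timp2 had 0.3341 and Zbp1 -0.1962.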

Other observations

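The tests of copy number, of knockout libraries with a low share of tags in peaks and of a copied Pgk1 promoter were chosen after the result was seen, as were the segments themselves and the term for the share of tags in peaks. The test of strain segments was also chosen then: it replaced a correlation over segments chosen from all 8 libraries, which was dropped because that choice can itself give a correlation between its parts.

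Outside the segments, 34 peaks changed, 13 higher and 21 lower in the knockout. The following were chosen after their values were seen, for genes of immune signalling. A peak in the 5' UTR of Tgfb3, a TGF-beta ligand (12:86078452–86078729), had 13.96 ± 1.46 CPM in knockout against 4.50 ± 1.59 in wild-type libraries (log2 1.62, SE 0.30, edgeR adjusted p = 0.00924). Lower peaks were an intron of Nod1, a sensor of bacterial peptidoglycan (6:54954687–54954918, log2 -3.34, SE 0.60, adjusted p = 0.00728), an intergenic peak assigned to the chemokine receptor gene Ccr6 (17:8228724–8228973, log2 -1.84, SE 0.31, adjusted p = 0.00321), an intron of the histamine receptor gene Hrh2 (13:54215854–54216099, log2 -2.09, SE 0.44, adjusted p = 0.0365) and an intergenic peak assigned to Ly6e (15:74931669–74931952, log2 -1.39, SE 0.29, adjusted p = 0.0386). The genotypes overlapped at the last 3: knockout replicate 1 had 21.72 CPM at the Ccr6 peak, 16.89 at the Hrh2 peak and 21.72 at the Ly6e peak, where the lowest wild-type libraries had 21.08 (replicate 2), 12.11 (replicate 4) and 17.57 (replicate 2). The Nod1 peak, with a mean of 8.25 tags, lay within 2 Mb of both changed Mturn peaks. The Hrh2 peak lay within 2 Mb of a changed Thoc3 peak. The Ccr6 peak lay within 2 Mb of a changed Tcp10a peak, itself within 2 Mb of the Tmem181a peak. These runs missed the segments only by the minimum of 4 calls, so these peaks do not stand apart from the clustering. Each of the 5 peaks lost the call without at least 1 library. The Ccr6 peak lost it without knockout replicate 3 (adjusted p = 0.0511, range 1.16e-05 to 1). The Tgfb3 peak lost it without wild-type replicates 1 (0.0567) or 4 (0.0538) or knockout replicate 4 (0.0649; range 0.00343 to 1), and the Nod1 peak without wild-type replicate 4 (0.0758) or knockout replicates 3 (0.104) or 4 (0.0563; range 0.000125 to 0.14). The Hrh2 peak lost it without wild-type replicates 1 (0.173), 2 (0.143) or 3 (0.15) or knockout replicates 3 (0.392) or 4 (0.197; range 2.62e-06 to 1), and the Ly6e peak without wild-type replicates 1 (0.179) or 3 (0.27) or knockout replicates 2 (0.0731), 3 (0.316) or 4 (0.196; range 0.00145 to 1).

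Changed peaks lay in chained segments: 65 of 99 fell in 6 segments of 19.2 Mb, where random draws of 99 tested peaks gave 0.961 chained calls on average and at most 14 (10000 draws, permutation p = 1e-04, the smallest they can give). The draws treat neighbouring peaks as independent, and the chaining rule was set after the calls were seen. In other splits of the 8 libraries with chained calls, 27.6% to 90% of calls were chained, against 65.7% in the real split. Splits without chained calls had at most 14 calls. The p therefore shows only that calls lay closer than independent peaks would, whatever the grouping. A copy number change would move all peaks of a segment by 0.585 (a gain of 1 copy) or -1 (a loss) on the log2 scale. The largest absolute segment median was 0.11 (SE 0.0941), below the bound of 0.3 set against it. With 2 SE added, 5 segments stayed at 0.298 or less, while that at 6:136464379 reached 0.418, past the bound but below a change of 1 copy. Without the knockout libraries of low share in peaks, 59 of the 65 calls still passed with the same sign. These calls thus did not rest on knockout replicates 1 and 2. In that fit both knockout libraries (20.9% and 26.2%) had a higher share of tags in peaks than every wild-type library (9.79% to 17.5%). The share was then confounded with genotype, so this count does not exclude an effect of the share. Segments of another strain fixed in the knockout line were tested by chaining the calls of 4 libraries, 2 of each genotype. Over peaks not called, the change in these libraries was correlated with that in the other 4. Chained from libraries numbered 1 and 2 the correlation was -0.144, and from those numbered 3 and 4 -0.0597. Both were below the medians of 1000 random sets (0.022 and 0.00787), so the repeat that this explanation needs was not found in these 2 choices. Of the tested peaks in their chains, 643 of 1423 and 853 of 1371 lay in the 6 segments. Over all choices this share ran from 20.2% to 100%, so the correlations do not cover the 6 segments alone. Every other choice of such 4 libraries was added after that result, and in all the correlation exceeded the 95th percentile of random sets in 22 of the 34 choices that gave a segment: 20 of 22 with knockout replicates 1 and 2 apart, but 2 of 12 with both on the same side, where the genotypes' shares of tags in peaks differed by at least 5.48 points, in opposite directions on the 2 sides. The test therefore leaves strain segments open, no sequence was examined, and loss of NLRP3 itself stays open and was not tested, since anything fixed in the knockout line is confounded with genotype.

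The Pgk1 promoter peak rose by a log2 change of 1.11 in the knockout, alike in all 4 libraries (97.05 to 103.8 CPM). Sex of the animals was argued against: with chromosome Y tags as a covariate the change was 1.18 (SE 0.162, adjusted p = 0.000468, within a range of 3.31e-07 to 1 over its alternatives). Targeting constructs often carry a copy of this promoter to drive a selection gene, and such a copy could add tags to this peak: the other Pgk1 peak and the promoter peaks within 5 Mb, 31 in all, had a median change of -0.0213 (-0.494 to 1.02), the highest at a Mir421 peak with an SE of 0.41 and an edgeR adjusted p of 0.942. The labels do not describe the construct, and a change of this promoter alone in microglia would give the same values, so a response to loss of NLRP3 stays open and was not tested.

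Other splits of the 8 libraries into 4 and 4 gave counts as large, so by the number of calls chance was not excluded for any of the 4 counts. With the real split included, 3 of 35 splits gave at least the real 99 called peaks (highest other 505), 3 gave at least 33 genes (highest other 52), 3 gave at least 65 chained calls (highest other 378) and 17 gave at least 2 gene lists (highest other 5). The other splits with at least 65 chained calls, 112 and 378, had them in chains of 0.173 and 3.67 Mb in all, against 19.2 Mb in the real split, and shared 0 calls with it. The split with 505 calls parted the libraries with the highest share of tags in peaks (wild-type replicates 1 and 4, knockout replicates 3 and 4) from those with the lowest, which points to a structure of the samples other than genotype. Of its calls, 155 lay on unplaced contigs. With this split as a term 125 peaks were called, all 99 real calls among them. The term is balanced between the genotypes, so it can hardly take up a genotype difference. Keeping the calls under it was therefore nearly fixed in advance.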
